A study of Homo sapiens with 12 samples.

How the data were processed

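RNA from MDA-MB-231 cells was sequenced in 4 groups of 3 libraries: DMSO (Ctrl), and SAHA, compound 1 and a6 at 2.5 µM for 48 h. The submitters' processing notes name cutadapt, DESeq2 and the GRCh38 (hg38) build; the aligner, the read counter and the versions are not given in the sources used here. Whether counting used strand is not given in the sources used here either. The labels call the libraries biological replicates and say no more about separate cultures, so p-values of single genes measure the spread between these libraries, part of which may be technical. Those of gene lists rest on the spread of the statistic across genes. Fisher's exact and Mantel-Haenszel tests count genes. None of these measures a spread between libraries.

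The files used were 3 comparison tables, 6 lists of changed genes and 6 lists of G4-related genes. In the comparison tables the authors give, per the file headers, a mean normalized count over the libraries compared (a signal that is never negative), a log2 fold change with its standard error, a Wald statistic (a score), a p-value and an adjusted p-value. Per the file headers, the deposited G4-related lists give a number of G4s per gene; only the names were used, and the region in which G4s were counted is not given in the sources used here. Checked on their own values, the deposited statistic equals the fold change over its standard error and the adjusted p-value a Benjamini-Hochberg adjustment over the genes of each table. The deposited lists of changed genes hold the genes with an unadjusted p-value under 0.05 and a change of at least 2-fold, with 0 mismatches. The lowest mean count was 2.44 in the SAHA table, 0.145 in the compound 1 table and 9.31 in the a6 table. The number of columns of values per library used was 0. Depth per library is unknown here, and exact intervals on shares cover the number of genes only. Counts partly rebuilt from printed digits were explored and not used here.

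The authors' DESeq2 Wald test at an adjusted p under 0.05, as deposited and with no fold limit, was the test of each compound against Ctrl. Mean levels in Ctrl and with a compound were computed from the mean count and the fold change, for equal groups. Differences between compounds are differences of deposited log2 fold changes, with the root of the summed squared standard errors, a two-sided z test and Benjamini-Hochberg adjustment; the shared Ctrl libraries make this conservative. Ctrl levels computed from different tables differed, after a constant, by a standard deviation of 0.00131 to 0.00326 on the log2 scale, against 1.76 or more across genes, so the same Ctrl libraries were taken to enter each table. Correlations and covariances were set beside simulated unchanged groups with the deposited standard errors and an error correlation of 0.5. In all, 36 gene lists were tested with limma cameraPR on the Wald statistic with a preset inter-gene correlation of 0.01, two-sided, adjusted over all lists and comparisons. An estimated correlation needs values per library and was not computed; a correlation of 0.05 was tried instead. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined; matching the G4-related lists by exact gene name, the list tests on differences and the alternatives named in the closing part were chosen after seeing the data.

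The genes named are, for each compound, the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean normalized count of at least 50 and no clone-type, LINC, antisense or small RNA name; for each difference the 5 highest and 5 lowest statistics past the threshold with the same filters; in each list up to 2 rising and 2 falling members with the smallest adjusted p; in each G4-related list the 5 with the smallest adjusted p; and MYC, BCL2, KIT, VEGFA, TERT and CDKN1A. Some genes that this rule takes are not reported here. Members of the PSG and CDCA families were chosen after their values were seen. Positions, transcript length and GC content come from GENCODE 29 on GRCh38, which matched 98.3% of SAHA, 97.0% of compound 1 and 98.9% of a6 genes; genes given a position are protein-coding there.

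Alternatives were a 2-fold limit, an adjusted p under 0.01, adjustment over all genes, a mean count of at least 10, centring on the median fold change and the authors' lists; for differences an error correlation of 0.5; for correlations a mean count of at least 50; for lists a correlation of 0.05, ranks and a mean count of at least 50; for G4 shares a 4-fold limit. Removal of a lowess trend of fold change on GC content (share 0.3), division of the compound 1 statistic by its own spread, and for G4 shares bins of GC content, all listed names and an adjusted p under 0.05 were added after seeing the data. The tests were tested on simulated data with 200 changed genes, all with a mean normalized count of at least 50, and errors drawn from the deposited standard errors. Recovery among genes with lower counts was not simulated. With the SAHA standard errors over 18534 genes 97.0% of these 4-fold and 37.3% of these 2-fold changes were called, and with those of a6 over 15255 genes 100% and 59.7%. Of the simulated calls 2.13% for SAHA, 2.08% for compound 1 and 7.87% for a6 were unchanged genes. For the difference of a6 and SAHA 87.0% of 4-fold and 13.5% of 2-fold differences were called. The errors of both compounds were drawn independently there, without shared Ctrl libraries, so these shares may not hold for the deposited tables. In the list simulation the shifted list was called in each comparison and 0 others were. Its statistics were drawn independently between genes, so it does not test lists whose members vary together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.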

Results

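MDA-MB-231, an established human triple-negative breast cancer cell line, was treated for 48 h with DMSO (Ctrl) or with 1 of 3 compounds at 2.5 µM, and RNA was sequenced. The compounds were SAHA, compound 1 and a6. SAHA is vorinostat, an inhibitor of histone deacetylases (HDACs). The labels describe SAHA and compound 1 as acting on a single target, and a6 as acting on both HDACs and G-quadruplexes (G4s), structures that guanine-rich nucleic acid can form. Each of the 4 groups had 3 libraries, 12 in all. The measurements are the authors' comparisons of each compound with Ctrl, over 18534 genes for SAHA, 27126 for compound 1 and 15255 for a6. The tables give a mean normalized read count per gene and no total per library, so the depth of each library is unknown here. The median of these mean counts over genes was 147 in the SAHA table, 23.0 in the compound 1 table and 231 in the a6 table.

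The comparison of SAHA with Ctrl shows what an HDAC inhibitor alone did in these cells. SAHA raised 839 genes and lowered 560 at an adjusted p under 0.05 in the authors' deposited table, and 774 and 390 of these changed at least 2-fold. Relative to other genes, cell cycle and DNA replication genes were displaced downwards. The neuronal genes measured with SAHA were displaced upwards, which may partly reflect which of them entered the SAHA table. CPA4, a secreted carboxypeptidase, had the smallest adjusted p: its log2 fold change in the authors' deposited table was 3.15 with a standard error of 0.26 and an adjusted p of 2.32e-30. CPA4 lies at chromosome 7, 130293134 to 130324180, on GRCh38, and its mean normalized count computed from the authors' deposited table was 645 in Ctrl and 5730 with SAHA. TSPOAP1, at chromosome 17, 58301228 to 58328760, fell by 3.01 on the log2 scale with a standard error of 0.37 and an adjusted p of 4.80e-13 in the authors' deposited table.

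**Figure D1:**
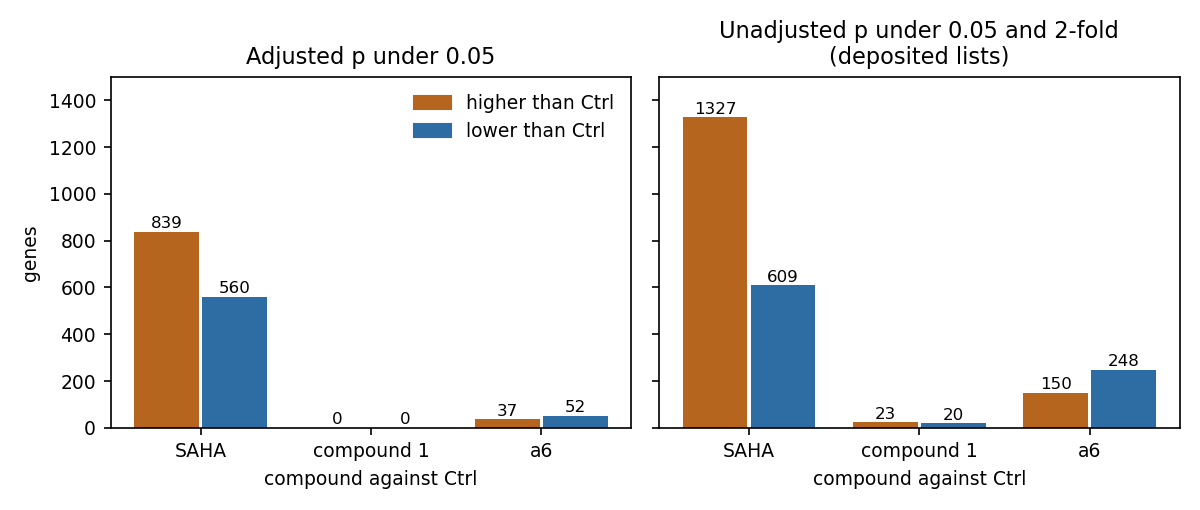
Number of genes higher (brown) and lower (blue) than Ctrl for each compound. On the left, genes with an adjusted p under 0.05 in the authors' deposited table number 839 and 560 for SAHA, 37 and 52 for a6 and 0 for compound 1; on the right, the authors' lists by unadjusted p and 2-fold change hold 1327 and 609, 150 and 248, and 23 and 20.

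In the neuronal list with SAHA, of 14 measured members, 4 rose and 0 fell over all genes, and 6 rose and 0 fell when adjusted over the list alone, with a median log2 fold change of 1.39 (limma cameraPR, adjusted p = 1.71e-07). The lowest mean normalized count in the SAHA table, over Ctrl and SAHA libraries together, was 2.44. A member near 0 in Ctrl therefore entered it only if its count was higher with SAHA. Of this list, 20 members were measured with compound 1 and 6 with a6. The median and the list test with SAHA may thus be partly set by which members entered. SCG2, a secretory granule protein of neuroendocrine cells, rose by 5.25 with a standard error of 0.56 and an adjusted p of 7.94e-18 in the authors' deposited table. MAP2, a microtubule-associated protein of dendrites, rose by 4.49 with 0.51 and 7.94e-16 in the authors' deposited table. Other high log2 fold changes in the authors' deposited table, among genes with a mean normalized count of at least 50, were 6.58 with 0.92 as standard error for HPCAL4, 6.32 with 0.80 for PHOSPHO1, 5.22 with 0.51 for KRTAP2-3, 5.17 with 0.51 for TRBV6-5, 4.96 with 0.58 for SERPINB7, 4.68 with 0.50 for PSG7, 4.46 with 0.58 for DCLK1 and 4.25 with 0.37 for C1orf116. PSG7, KRTAP2-3 and TRBV6-5 belong to families of similar sequence, so the share of reads that belongs to each is uncertain. Among the other lowered genes with such a mean count SLCO4A1 and DMTN were at -2.96 with 0.40 and -2.55 with 0.35 in the authors' deposited table. They were followed in the authors' deposited table by DHRS3, B3GNT8, TESMIN, GAREM2, PSMB10 and FN3K between -2.51 and -2.34. The other lists of cell type markers were not called, although single members rose in the authors' deposited table, among them the endothelial receptor KDR at 1.56 with 0.39, the monocyte marker CD14 at 1.81 with 0.42 and the cancer testis gene SPANXB1 at 2.01 with 0.39. Other members went the other way: in the endothelial list 2 rose and 1 fell over all genes. The haematopoietic list of CD14 had a median of -0.55 with 3 of 8 members above 0. In the cancer testis list all 7 measured members were above 0. With compound 1, 12 of that list were measured, so the same limit of the SAHA table applies.

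Cell cycle and mitosis genes shifted down with SAHA: of 36 measured members, 0 rose and 17 fell over all genes, and 0 rose and 23 fell when adjusted over the list alone (cameraPR, adjusted p = 6.11e-17). Their median log2 fold change was -0.93. Replication-dependent histone genes, listed as a sign of RNA quality, had a median of -1.15 with 1 of 11 members above 0, of which 0 passed over all genes and 2 fell when adjusted over the list alone (cameraPR, adjusted p = 0.0764, and 0.0307 on ranks). PLK1, a mitotic kinase, fell by 1.33 on the log2 scale with a standard error of 0.26 and an adjusted p of 1.96e-05 in the authors' deposited table. KIF20A, a kinesin of cytokinesis, fell by 1.74 with 0.31 and 2.62e-06 in the authors' deposited table. In the DNA replication list, of 40 measured members, 0 rose and 6 fell over all genes, and 0 rose and 11 fell when adjusted over the list alone (cameraPR, adjusted p = 1.50e-05). LIG1, the replicative DNA ligase, was at -1.12 with 0.28 and CDC45, a part of the replicative helicase, at -1.07 with 0.29 in the authors' deposited table. In the homologous recombination and Fanconi list, of 35 measured members, 0 rose and 2 fell over all genes, and 0 rose and 2 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00370, and adjusted p = 0.0872 with an inter-gene correlation of 0.05). RAD54L, a recombination motor protein, fell by 1.76 with a standard error of 0.27 in the authors' deposited table. FANCA was at -0.84 with 0.27 in the authors' deposited table (adjusted p = 0.0277) and at -0.74 with the trend on GC content removed (adjusted p = 0.0730), so most of its change remained without the call.

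Among genes widely raised by HDAC inhibitors, of 24 measured members, 6 rose and 1 fell over all genes, and 8 rose and 1 fell when adjusted over the list alone with SAHA (cameraPR, adjusted p = 0.0148, and adjusted p = 0.129 with an inter-gene correlation of 0.05). CDKN1A, the cell cycle inhibitor p21, rose by 1.26 with a standard error of 0.34 and an adjusted p of 0.00666 in the authors' deposited table. In the authors' deposited table CCN2 rose by 1.20 with 0.29 and 0.00166, and DHRS2 by 4.23 with 0.97 and 0.000654. The member that fell was the histone gene H2BC21, at -2.29 with 0.65 and a mean normalized count of 17.3 in the authors' deposited table. Of the 17 measured HDAC and sirtuin genes, 0 passed with SAHA, compound 1 or a6 in the authors' DESeq2 test, over all genes and when adjusted over the list alone.

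Oncogenes known for G4s in their promoters shifted down with SAHA: of 25 measured members, 0 rose and 6 fell over all genes, and 0 rose and 6 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00192). TYMS, thymidylate synthase, fell by 1.41 on the log2 scale with a standard error of 0.25 and an adjusted p of 2.23e-06 in the authors' deposited table. TERT, the catalytic subunit of telomerase at chromosome 5, 1253147 to 1295069, fell by 1.53 with 0.41 and 0.00468 in the authors' deposited table. MYC, BCL2 and VEGFA were at 0.27 with 0.34, 0.23 with 0.36 and -0.71 with 0.35 in the authors' deposited table and did not pass. Among G4 helicases and binding proteins, of 26 measured members, 0 rose and 1 fell over all genes, and 0 rose and 1 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00431, and adjusted p = 0.0701 with an inter-gene correlation of 0.05). The member that fell was the helicase PIF1, at -1.42 with 0.31 in the authors' deposited table.

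NF-kB and inflammatory genes shifted down with SAHA: of 26 measured members, 1 rose and 6 fell over all genes, and 2 rose and 9 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00225). TNFAIP2 fell by 1.82 with a standard error of 0.26 and the cytokine gene IL1A rose by 1.92 with 0.51 in the authors' deposited table. In the interferon response list, of 34 measured members, 1 rose and 6 fell over all genes, and 1 rose and 7 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00564, and adjusted p = 0.108 with an inter-gene correlation of 0.05). ISG15 and OASL were at -1.42 with 0.31 and -1.86 with 0.35, and IFI6, the member that rose, at 2.08 with 0.37 in the authors' deposited table. The mesenchymal list was not called (cameraPR, adjusted p = 0.405): COL6A3 and CDH2 rose by 1.78 with a standard error of 0.29 and 3.17 with 0.72 in the authors' deposited table. In the same list COL6A1 and FOSL1 fell by 0.97 with 0.31 and 0.90 with 0.28 in the authors' deposited table. With the trend on GC content removed from the authors' deposited table COL6A1 was at -0.70 (adjusted p = 0.179) and FOSL1 at -0.70 (adjusted p = 0.130), so most of each change remained without the call. That removal moved the SAHA counts to 909 higher and 331 lower, 73.3% higher against 60.0% as deposited.

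The comparison of compound 1 with Ctrl shows what the other single-target compound did. In the authors' DESeq2 test 0 of 27126 genes passed an adjusted p of 0.05 and 54 had an unadjusted p under 0.05, where chance gives 1356. Dividing the statistic by its own spread, an alternative chosen after seeing the data, called 61 genes, 10 of them with a mean normalized count of at least 50. On simulated data with the standard errors of this comparison, 89.4% of 4-fold and 40.3% of 2-fold changes put in at a mean normalized count of at least 50 were called, so changes of 2-fold could be missed. The simulated statistic of unchanged genes had a spread of 1, while the observed spread over such genes was 0.504. These shares may therefore not hold for the deposited table. In the authors' deposited table, with standard errors, MYC, BCL2, TERT, VEGFA and CDKN1A were at 0.18 with 0.49, 0.20 with 0.40, -0.28 with 0.38, 0.26 with 0.51 and 0.29 with 0.50. KIT was measured in this table alone, at a mean normalized count of 0.172 in the authors' deposited table.

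Of the 36 gene lists, 11 were displaced from the other genes with compound 1, with 0 members past the threshold in each, over all genes and when adjusted over the list alone. The p-values of these lists rest on the spread across genes and not between libraries. NF-kB and inflammatory genes had a median log2 fold change of 0.53, with 24 of 30 above 0 (cameraPR, adjusted p = 2.58e-07). Unfolded protein and ATF4 response genes had a median of 0.22, with 28 of 33 above 0 (cameraPR, adjusted p = 2.23e-07). Ribosome biogenesis genes lay at 0.15 (cameraPR, adjusted p = 0.00107). Mitochondrially encoded genes, listed as a sign of RNA quality, lay lower, at -0.23 with 0 of 13 above 0 (cameraPR, adjusted p = 2.75e-07). Whether RNA quality differed between these libraries and Ctrl was not tested. Also lower were hypoxia and glycolysis genes at -0.17 (cameraPR, adjusted p = 1.50e-05) and cholesterol synthesis genes at -0.13 (adjusted p = 5.82e-05). Haematopoietic genes lay at -0.58 (cameraPR, adjusted p = 0.00359, and adjusted p = 0.0596 over genes with a mean count of at least 50). The other 4 lists were called at an adjusted p of 0.0129 for mesenchymal genes, 0.0260 for interferon response genes, 0.0260 for antigen presentation genes and 0.0107 for ribosomal proteins (cameraPR), with medians of -0.09, 0.12, -0.10 and -0.09. With an inter-gene correlation of 0.05 their adjusted p was 0.148, 0.204, 0.182 and 0.182. With the trend on GC content removed, antigen presentation genes had an adjusted p of 0.0704 (cameraPR).

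The comparison of a6 with Ctrl shows what the dual-target compound did. It raised 37 genes and lowered 52 at an adjusted p under 0.05 in the authors' deposited table, 35 and 45 of them at least 2-fold. Hypoxia and glycolysis genes and mesenchymal genes were displaced downwards relative to other genes. TAGLN, an actin-binding protein of contractile cells at chromosome 11, 117199321 to 117204782, fell by 2.10 on the log2 scale with a standard error of 0.28 and the smallest adjusted p, 5.91e-10, in the authors' deposited table. CA9, a carbonic anhydrase induced by hypoxia at chromosome 9, 35673856 to 35681159, fell by 2.76 with a standard error of 0.45 and an adjusted p of 1.88e-06 in the authors' deposited table, from a mean normalized count of 499 in Ctrl to 73.5. CEMIP, which takes part in hyaluronan breakdown and lies at chromosome 15, 80779343 to 80951776, fell by 2.35 with 0.34 and 2.56e-08 in the authors' deposited table. CGN, the tight junction protein cingulin at chromosome 1, 151510510 to 151538692, rose by 2.33 with 0.37 and 1.88e-06 in the authors' deposited table. HSD11B1, which converts cortisone to cortisol, and TRNP1, a nuclear protein, rose by 2.37 with 0.47 and 1.73 with 0.28 in the authors' deposited table. Other lowered genes with a mean normalized count of at least 50 in the authors' deposited table were PI16, ALDOC, PPFIA4, ANXA8L1, PHYHD1 and HTRA3, between -2.18 and -1.82. Other raised ones with such a mean count were TAS1R3, FGGY, KIAA1755, LNCOG, SP140, IFI6 and FLI1, of which TAS1R3 was highest at 1.80 with 0.48 in the authors' deposited table. ANXA8L1 resembles other ANXA8 copies, so its value is uncertain.

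**Figure D2:**
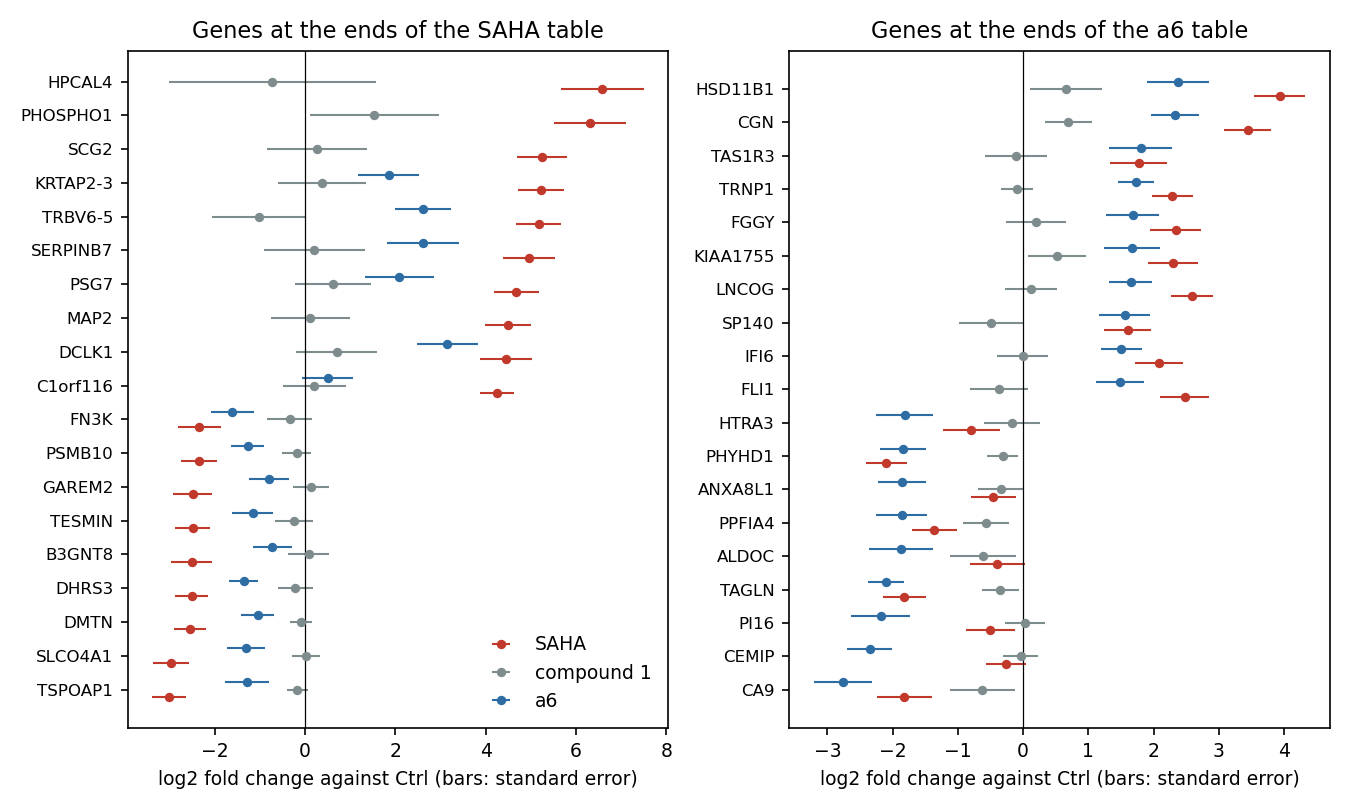
Log2 fold change against Ctrl of genes at both ends of the SAHA table (left) and the a6 table (right), with a mean normalized count of at least 50 there, for SAHA (red), compound 1 (grey) and a6 (blue), with bars of 1 standard error, from the authors' deposited table of each compound; a gene that the a6 table lacks has no blue point. CEMIP lies at -2.35 with a6 and -0.27 with SAHA, and TAGLN at -2.10 and -1.82.

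In the hypoxia and glycolysis list with a6, of 32 measured members, 0 rose and 2 fell over all genes, and 0 rose and 6 fell when adjusted over the list alone, with a median log2 fold change of -0.42 (cameraPR, adjusted p = 1.12e-12). The members that fell over all genes were CA9 and the glycolytic enzyme ALDOC, the latter at -1.87 with 0.49 in the authors' deposited table. In the mesenchymal list, of 31 measured members, 0 rose and 2 fell over all genes, and 1 rose and 7 fell when adjusted over the list alone, with a median of -0.34 (cameraPR, adjusted p = 7.97e-07). The members that fell over all genes were LOX, which cross-links collagen, at -1.18 with 0.24 and an adjusted p of 0.000583, and the collagen gene COL5A1 at -0.93 with 0.22 and 0.0106 in the authors' deposited table. In the fibroblast list, of 6 measured members, 0 rose and 1 fell over all genes, and 0 rose and 2 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00288), and the member over all genes was PI16 at -2.18 with 0.45 in the authors' deposited table. In the interferon response list, of 31 measured members, 1 rose and 1 fell over all genes, and 1 rose and 4 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00310, and adjusted p = 0.0701 with an inter-gene correlation of 0.05). OASL fell by 1.54 with a standard error of 0.30 and an adjusted p of 0.000298 in the authors' deposited table, while IFI6 rose 2.84-fold. Among aryl hydrocarbon receptor targets, of 7 measured members, 0 rose and 1 fell over all genes, and 0 rose and 1 fell when adjusted over the list alone (cameraPR, adjusted p = 0.00564, and adjusted p = 0.0582 on ranks). CYP1B1, a xenobiotic-metabolizing enzyme, was the member that fell, at -1.71 with 0.30 in the authors' deposited table. Ribosome biogenesis genes were displaced upwards with a median of 0.14 and 0 of 35 members past the threshold, over all genes and when adjusted over the list alone (cameraPR, adjusted p = 0.00564, and adjusted p = 0.108 with an inter-gene correlation of 0.05).

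G4 promoter oncogenes were displaced downwards with a6, with 0 of 24 members past the threshold over all genes and when adjusted over the list alone (median -0.25, cameraPR, adjusted p = 0.0329, and adjusted p = 0.182 with an inter-gene correlation of 0.05). MYC was at -0.33 with 0.30, BCL2 at 0.25 with 0.33, TERT at -0.39 with 0.38, VEGFA at -0.59 with 0.30 and CDKN1A at 0.74 with 0.30 as standard error in the authors' deposited table, and none of these passed. The lists not called with a6 include cell cycle genes (median -0.11, cameraPR, adjusted p = 0.278) and genes widely raised by HDAC inhibitors (median -0.26, adjusted p = 0.0927).

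**Figure D3:**
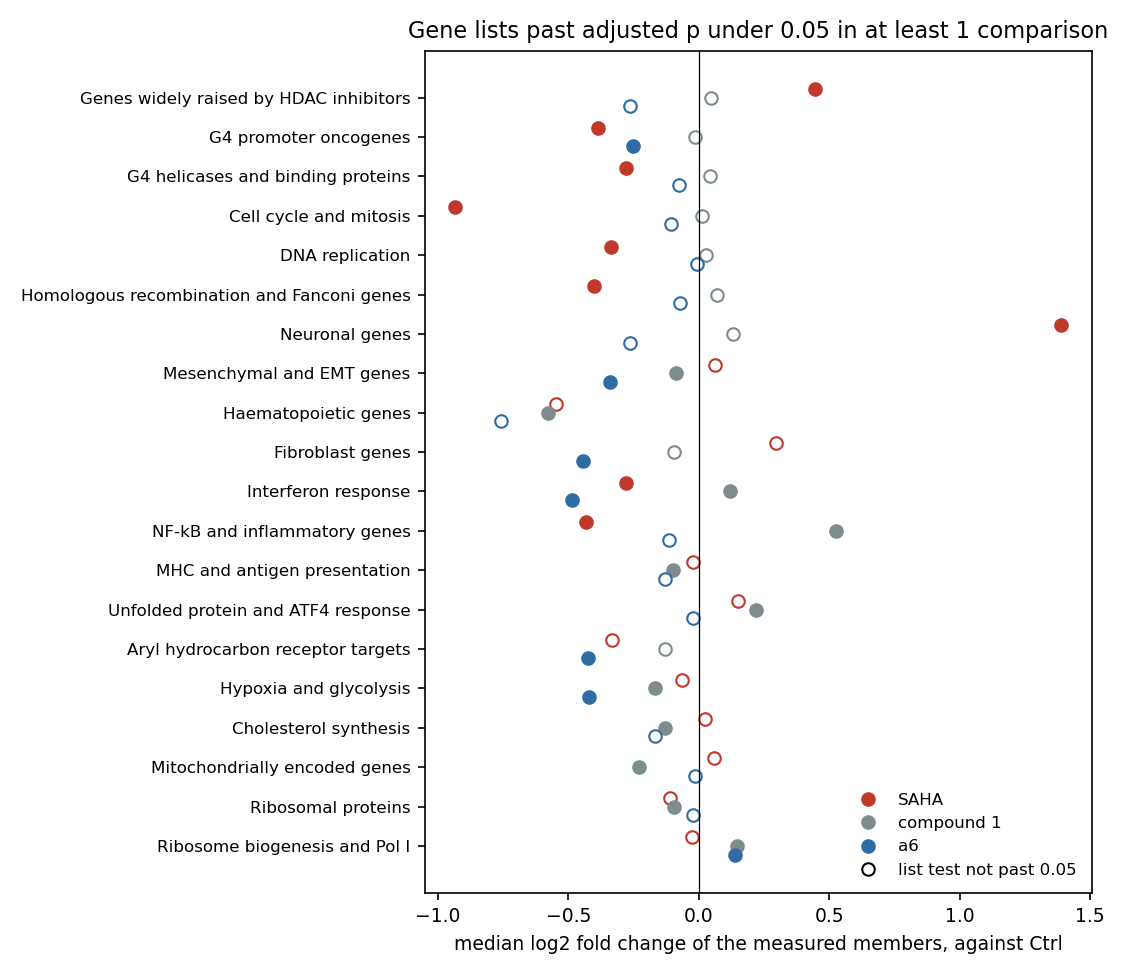
Median log2 fold change against Ctrl of the measured members of each gene list called in at least 1 comparison, for SAHA (red), compound 1 (grey) and a6 (blue); filled points passed cameraPR at an adjusted p under 0.05 and open points did not. Cell cycle genes lie at -0.93 and neuronal genes at 1.39 with SAHA, and hypoxia and glycolysis genes at -0.42 with a6.

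The comparison of a6 with SAHA asks where the dual-target compound differed from the HDAC inhibitor at the same dose and time. Of 15255 genes in both tables, 39 differed at an adjusted p under 0.05 (z test, values computed from the authors' deposited table), with a6 higher for 9 and lower for 30. These tables share 591 of the 839 genes raised by SAHA and 557 of the 560 it lowered. Genes raised by SAHA that the a6 table lacks could not be tested, so differences with a6 lower may be missed. CPA4 was lower with a6 than with SAHA, a difference of -2.66 with a standard error of 0.33 (adjusted p = 1.81e-11), from the authors' deposited table. LMCD1, IGFBP3, AQP3 and TNC were also lower, with differences of -2.08, -1.82, -2.13 and -1.67 and standard errors of 0.41, 0.37, 0.44 and 0.35, from the authors' deposited table. PHF19, a Polycomb-associated protein, was higher by 1.77 with 0.32 in the authors' deposited table. So were SYDE1 by 1.65 with 0.33, ESPL1, the protease separase, by 1.54 with 0.37, RAD54L by 1.49 with 0.36 and IQGAP3 by 1.44 with 0.34, from the authors' deposited table. CEMIP was lower with a6, a difference of -2.09 with 0.46 (adjusted p = 0.00601), from the authors' deposited table. For TAGLN the difference in the authors' deposited table was -0.28 with a 95% interval of -1.11 to 0.56, and for CA9 -0.94 with -2.15 to 0.26. In the authors' deposited table it was -0.55 with -1.38 to 0.28 for TRNP1, for CDKN1A -0.52 with -1.42 to 0.38 and for MYC -0.60 with -1.48 to 0.28; none of these passed. The test treats the errors of both tables as independent, although the Ctrl libraries are shared. With an error correlation of 0.5 it called 540 genes.

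For gene lists, tested on the difference after the separate comparisons had been seen, a6 lay above SAHA for cell cycle genes (35 members in both tables, cameraPR, adjusted p = 4.61e-19) and DNA replication genes (40, adjusted p = 2.28e-08). It lay below SAHA for mesenchymal genes (31 members, cameraPR, adjusted p = 5.23e-07), genes widely raised by HDAC inhibitors (21, adjusted p = 7.27e-06), hypoxia and glycolysis genes (32, adjusted p = 3.79e-05) and neuronal genes (6, adjusted p = 0.000188). The a6 table lacks SCG2 and MAP2, so the neuronal difference rests on other members.

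Many genes changed by a6 were also changed by SAHA. All 37 genes raised by a6 had a positive fold change with SAHA and 32 passed there, where independent lists would share 1.43. Of the 52 genes lowered by a6, 48 were below 0 with SAHA and 26 passed, against 1.90 for independent lists. The planned hypergeometric p is not used, since the shared Ctrl libraries, too few to be split, make the lists dependent, and part of the excess and of the shared direction may come from them. The planned overlap of simulated unchanged groups is not used either, since such groups hold almost no calls to share. In the 591 genes raised by SAHA that are in both tables, the median log2 fold change computed from the authors' deposited table was 1.60 with SAHA and 0.52 with a6. In the 557 genes lowered by SAHA that are in both tables it was -1.14 and -0.40. The rest of the 839 genes raised by SAHA are missing from the a6 table and do not enter these medians. In the genes raised by a6 the median in the authors' deposited table was 2.29 with SAHA and 1.67 with a6, and in those lowered by a6 it was -0.95 and -1.37. Choosing genes by their call with a compound favours larger values with that compound, so these medians do not rank the compounds. Across genes, which are not independent replicates, the fold changes of both compounds had a Pearson r of 0.57 and a Spearman rho of 0.48, against a simulated r of 0.49 for shared controls alone. The covariance was 0.165 against 0.0802 simulated. The simulated values may be too high, since the observed ones for both pairs with compound 1, given below, were lower than those simulated.

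**Figure D4:**
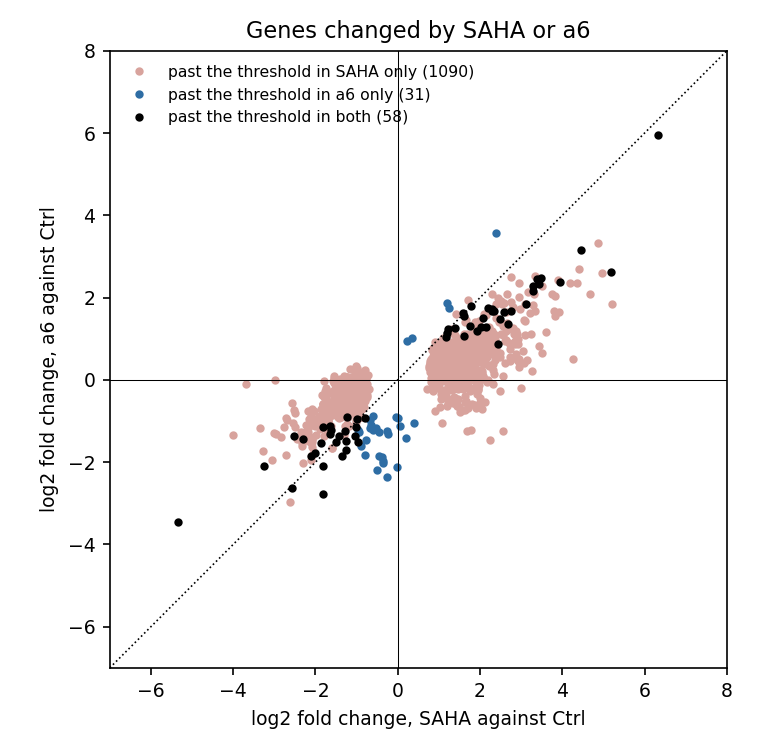
Log2 fold change with a6 (vertical axis) against that with SAHA (horizontal axis) for genes in both tables and past an adjusted p of 0.05 with either compound, from the authors' deposited table of each. The dotted line marks equal change. Genes changed by SAHA that the a6 table lacks are not shown. Black points passed with both (58), blue with a6 only (31) and pink with SAHA only (1090).

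The comparisons with compound 1 ask where the other compounds differed from it. It differed from a6 at 5 of 15251 genes and from SAHA at 197 of 18514 (z test), and with an error correlation of 0.5 at 44 and 987. At an unadjusted p under 0.05 there were 222 genes for a6 and 1345 for SAHA. Chance would give 763 and 926 if the errors of both tables were independent. The shared Ctrl libraries lower the number that chance gives. The 222 genes therefore do not show that a6 and compound 1 differed less than chance gives. TRNP1 was higher with a6 than with compound 1, by 1.83 with a standard error of 0.38 from the authors' deposited table. CEMIP, PLAAT4, OASL and TAGLN were lower with a6, with differences of -2.31, -1.83, -1.77 and -1.74 and standard errors of 0.43, 0.40, 0.37 and 0.40, from the authors' deposited table. The adjusted p of these differences, from the authors' deposited table, ranged from 0.00120 for CEMIP to 0.0336 for TAGLN. For MYC the interval of a6 minus compound 1 was -1.64 to 0.61 in the authors' deposited table. SAHA was higher than compound 1 for 108 genes, among them CPA4, TFPI2, RGS4, NPPB and PSG5 with differences of 3.26, 2.28, 3.16, 3.07 and 2.93 from the authors' deposited table. SAHA was lower for 89, among them TSPOAP1, SLCO4A1, PHF19 and DMTN with differences of -2.84, -2.98, -1.75 and -2.46 from the authors' deposited table. Among lists tested on the difference, a6 lay below compound 1 for hypoxia and glycolysis genes (cameraPR, adjusted p = 7.27e-06) and interferon response genes (adjusted p = 1.37e-05), and SAHA lay below it for cell cycle genes (adjusted p = 1.90e-19) and NF-kB genes (adjusted p = 1.09e-07). The fold changes had a Pearson r of 0.37 between a6 and compound 1 and 0.26 between SAHA and compound 1, and a Spearman rho of 0.33 and 0.23. Shared controls alone gave a simulated r of 0.49 and 0.48, and the covariances were 0.0412 and 0.116 against 0.0817 and 0.221 simulated.

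The authors also deposited lists of genes they relate to G4s, and the last comparison asks whether these make up different shares of the higher and lower genes in the authors' lists by unadjusted p and 2-fold change. Of the genes in those lists 1164 of 1936 for SAHA, 80 of 398 for a6 and 0 of 43 for compound 1 had an adjusted p under 0.05 in the authors' deposited table. The G4-related lists were drawn from these genes and are not independent evidence, so shares are compared with each other and not with the genome. With SAHA 292 of 609 lower genes (47.9%, exact 95% interval 43.9 to 52.0) and 535 of 1327 higher genes (40.3%, 37.7 to 43.0) were listed, an odds ratio of 1.36 (Fisher's exact test, two-sided, p = 0.00182, adjusted p = 0.0164 over 9 tests). When lower and higher genes were compared within bins of transcript GC content, the odds ratio was 1.01 and did not pass the Mantel-Haenszel test, an alternative chosen after seeing the data. With a6 118 of 248 lower and 58 of 150 higher genes were listed (Fisher's exact test, p = 0.0957, adjusted p = 0.431), and with compound 1 7 of 20 and 7 of 23 (adjusted p = 1). The lists of a6 and SAHA overlap, with 118 of 150 higher and 103 of 248 lower a6 genes also listed for SAHA, so the planned test of shares between these compounds is not of separate sets and is not used. Listed genes with small adjusted p in the authors' deposited table were CPA4, MAP2, TSPAN13, PCDH1 and AL365181.3 among genes raised by SAHA, and SLCO4A1, PHF19, DMTN and TNFAIP2 among those it lowered. They were TRNP1, AL365181.3, TLE2, FGGY and SP140 among genes raised by a6, and TAGLN, CEMIP, CYP1B1, PLAAT4 and PHYHD1 among those it lowered.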

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

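No test in this part was chosen after the result was seen. Named genes were flagged if their fold changes with 2 compounds had opposite signs, each with an unadjusted p under 0.05, and the z test of the difference passed. AQP3 and TNC met this rule with a6 and SAHA. Their opposite signs and passing differences are therefore how they were chosen and not further support. For AQP3, a water and glycerol channel at chromosome 9, 33441154 to 33447633, the log2 fold change in the authors' deposited table was -1.06 with a standard error of 0.31 with a6 (adjusted p = 0.0831) and 1.07 with 0.32 with SAHA (adjusted p = 0.0150). The difference of a6 minus SAHA in the authors' deposited table was -2.13 (adjusted p = 0.00280). For TNC, the matrix protein tenascin C at chromosome 9, 115019578 to 115118257, the values in the authors' deposited table were -0.76 with 0.24 (adjusted p = 0.136) and 0.91 with 0.26 (adjusted p = 0.00933), a difference of -1.67 (adjusted p = 0.00330). Against Ctrl, neither gene passed with a6 alone.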

How the results depend on the processing

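The GC trend removal, the rescaled statistic and the G4 comparison within GC bins were chosen after seeing the data, and the cause of a change was not tested unless given. The tables used give no depth and no value per library, so refits from counts, leaving out each replicate and other splits of the libraries were not run. No paired analysis was possible because the comparison tables used here give no value per library. At an adjusted p under 0.01 SAHA changed 820 genes and a6 36, fewer by construction. The authors' lists, by unadjusted p, hold 43 genes for compound 1 and 398 for a6, and share 221 between a6 and SAHA, 3 between a6 and compound 1 and 10 between SAHA and compound 1. Dividing the compound 1 statistic by its own spread called 61 genes, 10 with a mean count of at least 50. An error correlation of 0.5, which shrinks the standard errors, called 540 differences between a6 and SAHA, 44 between a6 and compound 1 and 987 between SAHA and compound 1. With the GC trend removed, the share of higher calls was 11.3% against 23.1% for a6 minus SAHA and 67.2% against 54.8% for SAHA minus compound 1. At a mean count of at least 50 the correlation with compound 1 was 0.33 for a6 and 0.23 for SAHA. An inter-gene correlation of 0.05, which widens the null by construction, left 16 of 27 list calls, 5 for SAHA, 7 for compound 1 and 4 for a6. The SAHA difference in G4-related share did not pass at 4-fold (odds ratio 1.54) or within GC bins (1.01). Among genes with an adjusted p under 0.05, also chosen after seeing the data, the odds ratio was 1.41. It passed there (Fisher's exact test, p = 0.00608, not adjusted over tests). Of the named genes 11 lost their call with the GC trend removed and 3 with centring, all for SAHA. None of them changed direction. For FANCA, COL6A1 and FOSL1, given above, most of the change remained with the GC trend removed, so a lost call is not a lost change. Lists gained a call in the main direction: on ranks replication-dependent histone genes with SAHA (adjusted p = 0.0307), oxidative phosphorylation with compound 1 (0.0281) and NRF2 targets with a6 (0.0307); at a mean count of at least 50 oxidative phosphorylation with compound 1 (0.0467); and with the GC trend removed that list (0.0134) and immediate early genes (0.0213) with compound 1. Counts in a single direction moved by over 1.5 times where totals did not: SAHA higher genes from 839 to 1327 with the authors' lists, and with the GC trend removed SAHA lower genes from 560 to 331, lower differences of a6 minus SAHA from 30 to 47 and of SAHA minus compound 1 from 89 to 59. Under the other alternatives run, total counts stayed within 1.5 times and no called gene or list changed direction. Adjustment over all genes of each table repeated the deposited adjustment, so it could not change a call and is no check.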

Other observations

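The tests of gene families, of the compound 1 statistic, of the GC trend, of a GC bias of the Ctrl libraries and of parts of symbols were chosen after the result was seen. Pregnancy-specific glycoprotein genes (PSG), a family normally expressed in placenta, rose with SAHA: 10 of 11 measured members passed, where 0.545 would by chance (Fisher's exact test, one-sided, adjusted p = 1.51e-09 over 1724 tests of symbol families). In the authors' deposited table PSG9 was at 3.61 with 0.38 as standard error, PSG1 at 2.84 with 0.33, PSG5 at 2.85 with 0.30 and PSG4 at 2.11 with 0.27. These genes resemble each other closely, so the members are not separate measurements. Among genes that SAHA lowered, 4 of 7 members of the cell division cycle associated family (CDCA) passed, where 0.243 would by chance (Fisher's exact test, one-sided, adjusted p = 0.0400). They were CDCA8 at -1.30 with 0.27, CDCA3 at -1.27 with 0.27, CDCA7 at -1.16 with 0.32 and CDCA5 at -1.01 with 0.29 in the authors' deposited table.

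The compound 1 statistics were narrower than chance gives, with 54 genes at an unadjusted p under 0.05 where 1356 were expected. With no change and accurate standard errors the spread of the statistic would be 1, but over genes with a mean normalized count of at least 50 it was 0.504. Low counts do not account for it, since the spread was 0.431 at a mean of at least 1000. A candidate explanation is that the deposited standard errors exceed the error of the fold changes, through deviations shared by libraries of different groups or too large a fitted spread: over genes with a mean normalized count of at least 50 the covariance of a6 and compound 1 fold changes was 0.377 of that simulated from these standard errors. Which of these holds stays open without values per library, as does a small effect of compound 1. Dividing the statistic by its spread called 61 genes, but 37 of them had a mean normalized count under 10 and 10 at least 50, so genes near the floor carry most of that count.

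Genes lowered by SAHA were concentrated in GC-rich transcripts, with 260 lower calls in the richest of 5 equal bins and 22 in the poorest, a ratio of shares of 11.8. With the trend of fold change on GC removed they were 106 and 23, a ratio of 4.61, which argues against that trend as the whole cause. Higher counts of GC-rich genes alone do not account for it either, as the odds ratio within bins of the mean count was 12.4 (95% interval 7.87 to 19.6). That odds ratio was computed with the GC trend left in. Whether the trend and the counts together account for the concentration was not tested. A GC bias of the Ctrl libraries alone would tilt the 3 comparisons alike, but the Spearman rho of fold change and GC across genes was -0.235 for SAHA, -0.384 for compound 1 and 0.0362 for a6. A bias that the a6 libraries share with Ctrl would leave the a6 comparison without a tilt, so these values cannot exclude it. Genes lowered by a6 lay in GC-rich transcripts as well, with 21 calls in the richest bin and 3 in the poorest, and 19 and 2 with the trend removed. Of the 52 genes lowered by a6, 26 were also lowered by SAHA, and the Ctrl libraries are shared. The a6 calls are therefore not a separate observation of the concentration. The comparison within bins of the mean count was not run for a6. A GC bias shared by the Ctrl and a6 libraries, a GC bias of the treated libraries and an effect of the compounds on GC-rich genes stay open, all untested.

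Counted per list, so that a name may recur, 562 names of the G4-related lists are not in the matching list of changed genes. Of these 100% contain the symbol of a changed gene as a part, against 0.508% of other names; in the list of genes lower with a6, C3 occurs in 111 of them and GAL in 45. A looser fold limit at the same p does not account for most of them, since 14.04% of the 356 measured ones had an unadjusted p under 0.05. A looser limit on p itself was not tested. Older symbols do not account for them either, as 0.712% shared an identifier or another symbol with a changed gene. This is consistent with a search by part of a symbol when the lists were made, a hypothesis about the files; no biological explanation was tested. Such names make up 63.8% of the list for genes lower with a6, and only exact names were counted above.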
